A study of Mus musculus with 12 samples.

How the data were processed

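Messenger RNA levels were measured by RNA sequencing in RAW264.7 cells, a mouse macrophage line, in 12 libraries from 4 groups of 3: untreated control, lipopolysaccharide (LPS), sodium propionate with LPS (SP+LPS) and sodium butyrate with LPS (SB+LPS). Per the labels, total RNA was extracted with a phenol-type reagent and a sequencing company prepared and sequenced the libraries. The authors counted reads per gene with featureCounts 1.5.0-p3 against the mouse build GRCm38; the aligner and the annotation release are not given in the sources used here. The deposited values are FPKM (fragments per kilobase of gene length, scaled to library size) for 54942 genes, with gene coordinates, length and type. Of these, 54409 gene identifiers occur in GENCODE vM21, and 53499 have the same start and end there.

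FPKM multiplied by gene length gave whole reads in each library, with 100% of nonzero values within 0.05 of a whole number after division by a common factor, and these recovered reads were used to give depth and to run one alternative. Summed reads ranged from 14065940 to 15714410 per library. The divisor behind the deposited FPKM was proportional to median-of-ratios size factors computed here from the recovered reads of 13932 genes with reads in all 12 libraries, so the deposited values were already scaled between libraries. The ratio of divisor to size factor was 14918500 in each library, with a spread of 1.4e-09 percent. Floors cover counting error only: where a group held no read of a gene, 3 reads in a library were taken as the limit.

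Genes with an FPKM of at least 1 in at least 3 libraries were tested, which left 12282 genes, of which 10007 are protein-coding and 262 have no symbol. Values were analysed as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, in one fit of 4 group means over all 12 libraries, with empirical Bayes moderation and a mean-variance trend. P-values are two-sided, were adjusted by the Benjamini-Hochberg method over the genes of each comparison, and were called at an adjusted p below 0.05. All adjusted p-values for genes are from limma. The comparisons were LPS against control, SP+LPS against LPS, SB+LPS against LPS and SB+LPS against SP+LPS. The labels do not say whether the replicates are separate cultures, so the p-values measure only the spread between these libraries, which may be technical.

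The gene lists, the comparisons, the alternatives except 3 and the rule for naming genes were written before the data were examined. There were 39 lists with 713 genes, of which 708 are in the table. The filter left, among others, 16 of 24 M1 effectors, 15 of 19 chemokines, 5 of 9 MHC class II and 10 of 13 osteoclast genes. It can admit a gene through 1 group alone, which favours rises in that group. Lists with at least 5 tested members, 31 of them, were tested against all other genes with camera in limma at a preset correlation between genes of 0.01, adjusted over the 31 lists of a comparison. They were tested again with an estimated correlation between genes, and with fry. Counts of members past the threshold are adjusted over all genes tested; they were also adjusted over the list alone, and that count is given where it differs. The named genes were a panel of 21 macrophage activation genes, the 8 protein-coding genes with the largest rise and the 8 with the largest fall in each comparison among those past the threshold, up to 4 members per list, and genes called in opposite directions for the 2 metabolites. The 8 largest needed a mean of at least 5 FPKM in the higher group and no overlap between the groups, which chance gives to 10% of genes with 3 against 3. Genes named outside that rule were chosen after their values were seen, as said where they appear.

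Alternatives were tried 1 at a time, and the closing section gives their effect: pseudocounts of 0.1 and 5, no filter, a mean FPKM of at least 5, median-of-ratios scaling, quantile normalization, no trend, voom on recovered reads, a fit of only the groups compared, a fold change of at least 2, replicate number as a block, and each library left out in turn. Chosen after seeing the data were scaling to summed reads, leaving out SP+LPS 2 and SB+LPS 2 together, and protein-coding genes alone. The tests were also run on simulated data with known changes, 1 draw per comparison. At a 2-fold change they recovered between 72.7% and 82.5% of changed genes, and at 4-fold between 84.8% and 95.3%. Between 9.21% and 12.9% of the calls in those draws were false, above the nominal 5%. Each draw changed between 63 and 67 tested genes at each fold and left at least 11916 unchanged. The real comparisons called far more genes than that, so the shares recovered and false do not carry over to the real calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. Any other data of the study were not analysed here.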

Results

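RAW264.7 macrophages were profiled in 12 libraries: 3 untreated, 3 with LPS (a bacterial cell wall component that activates macrophages through Toll-like receptor 4), 3 with sodium propionate and LPS, and 3 with sodium butyrate and LPS. Propionate and butyrate are short-chain fatty acids made by gut bacteria, and their chains differ by 1 carbon. In the metabolite groups, cells were kept with the metabolite for 24 h and then with metabolite and 1 µg/mL LPS for 6 h. The metabolite doses are not given, and the dose and time of the LPS group are not stated separately. Each library held between 14065940 and 15714410 reads. The first principal component carried 68.5% of the variance and the second 18.4%. LPS 1 lay apart from the other LPS libraries on the third, which carried 2.87%, and held 4.09% mitochondrial reads against 2.61% and 2.39%. The chi-square per gene between the reads of 2 libraries, expected from their total reads for genes with at least 20 reads in the pair, was 30.4 and 46.1 from LPS 1 to LPS 2 and LPS 3, against 5.95 between those. SB+LPS 3 also stood apart from its group, at 8.01 and 8.83 to SB+LPS 1 and SB+LPS 2 against 2.63 between those, and at 7.41 on the third component against -1.40 and -2.31. For SP+LPS 2 the values were 6.84 and 7.19, against 3.13 between SP+LPS 1 and SP+LPS 3. SP+LPS 2 had reads in 34886 genes and SB+LPS 2 in 24963, against 18411 to 19471 in the other libraries. Values for genes are mean FPKM ± SD (n = 3), and changes are log2 values from limma.

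LPS against control asks how the line responds to LPS, the background on which the metabolites were tested. LPS raised the acute inflammatory genes by large factors. Tnf, the early inflammatory cytokine, rose from 21.2 ± 0.873 to 1505 ± 264 FPKM. Il1b, the cytokine released after inflammasome cleavage, rose from 0.0376 ± 0.0326 to 1118 ± 41.4 FPKM, and Acod1, the enzyme that makes itaconate, from 1.80 ± 0.109 to 2436 ± 90.2 FPKM. Ptgs2, the inducible cyclooxygenase of prostaglandin synthesis, rose from 3.91 ± 0.471 to 890 ± 183 FPKM. The log2 changes were 6.07 for Tnf (SE 0.109, adjusted p = 2.51e-12), 10.07 for Il1b (SE 0.0826, adjusted p = 8.12e-15), 9.77 for Acod1 (SE 0.0567, adjusted p = 3.65e-16) and 7.49 for Ptgs2 (SE 0.130, adjusted p = 1.8e-12). Csf3, the granulocyte growth factor, had no read in control and 391.6 ± 57.8 FPKM with LPS, at least 3332-fold higher at a floor of 3 reads in a library. On GRCm38, Tnf (ENSMUSG00000024401) lies on chromosome 17 from 35199381 to 35202007, Il1b (ENSMUSG00000027398) on chromosome 2 from 129364570 to 129371139, and Csf3 (ENSMUSG00000038067) on chromosome 11 from 98701263 to 98703629.

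Gene groups moved with these genes. Of 20 cytokine genes tested 19 rose (median log2 change 2.51, or 2.37 with genes at 0 in control set to the floor; camera adjusted p = 1.23e-13). All 15 chemokine genes rose, among them the neutrophil attractant Cxcl2 (10.55) and the T cell attractant Ccl5 (7.28), with a list median of 4.03 (adjusted p = 1.28e-11). All 42 interferon-stimulated genes rose (median 2.86, adjusted p = 9.01e-28), among them the antiviral genes Rsad2 (5.71), Ifit1 (5.68) and Ifit3 (5.34). All 16 tested effectors of the M1 type, the inflammatory macrophage state, rose (median 2.48, adjusted p = 7.49e-12), including Nos2, the inducible nitric oxide synthase, from 0.00807 ± 0.0140 to 10.8 ± 0.522 FPKM. These 16 are the members of 24 listed that passed the filter. Nos2 passed it only through LPS-treated libraries, a route that favours rises. All 24 members of the NF-kB list of subunits and feedback genes rose (median 2.29, adjusted p = 2.99e-15), including the feedback inhibitors Tnfaip3 (4.04) and Socs3 (5.02). The NF-kB call was lost with an estimated correlation (adjusted p = 0.0539 with an estimated correlation), and the other 4 lists here kept theirs. Il10, an anti-inflammatory cytokine, stood at 0.0671 FPKM in control and 0.293 with LPS (adjusted p = 0.204), and Mrc1, a marker of the alternative M2 state, at 0.157 and 0.319 FPKM (adjusted p = 0.138). Of the panel, Il12b, Arg1 and Ffar2 stayed below the filter and were not tested.

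Proliferation genes fell in LPS. All 23 G1/S genes, which act at entry into DNA synthesis, fell (median -1.10, adjusted p = 1.43e-12). Tk1, thymidine kinase, went from 30.5 ± 1.92 to 3.83 ± 0.769 FPKM, and the replication licensing gene Cdc6 changed by -1.86. Of 24 G2/M genes, which act in mitosis, 20 fell and 1, Ube2c, rose (2 higher and 20 lower adjusted over the list alone; median -0.57, adjusted p = 6.28e-05). Mki67, the proliferation marker, fell from 112 ± 2.34 to 55.2 ± 17.5 FPKM. The G2/M call was lost with an estimated correlation (adjusted p = 0.13 with an estimated correlation), while that for G1/S was kept. The largest falls included Scd2, a fatty acid desaturase, from 162 ± 3.97 to 19.6 ± 1.59 FPKM, and Slc5a3, the inositol transporter, at -2.99. Csf1r, the receptor for the macrophage growth factor, fell from 202 ± 8.55 to 76.6 ± 5.42 FPKM.

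Limma called 3723 genes higher and 3369 lower in LPS than in control, 983 and 620 of them by at least 2-fold. The split depends on scaling: it was 2878 higher and 4116 lower with quantile normalization and 2019 and 5902 with scaling to summed reads, where the median of all genes moved from 0.03 to -0.26. Of the 31 lists 20 were called, 5 of them with an estimated correlation. Ribosomal protein genes show the limit this sets: 25 of 32 were called higher (26 adjusted over the list alone; median 0.36, camera adjusted p = 0.000262, adjusted p = 0.386 with an estimated correlation), while with quantile normalization the median was -0.23 and 18 were lower.

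**Figure D1:**
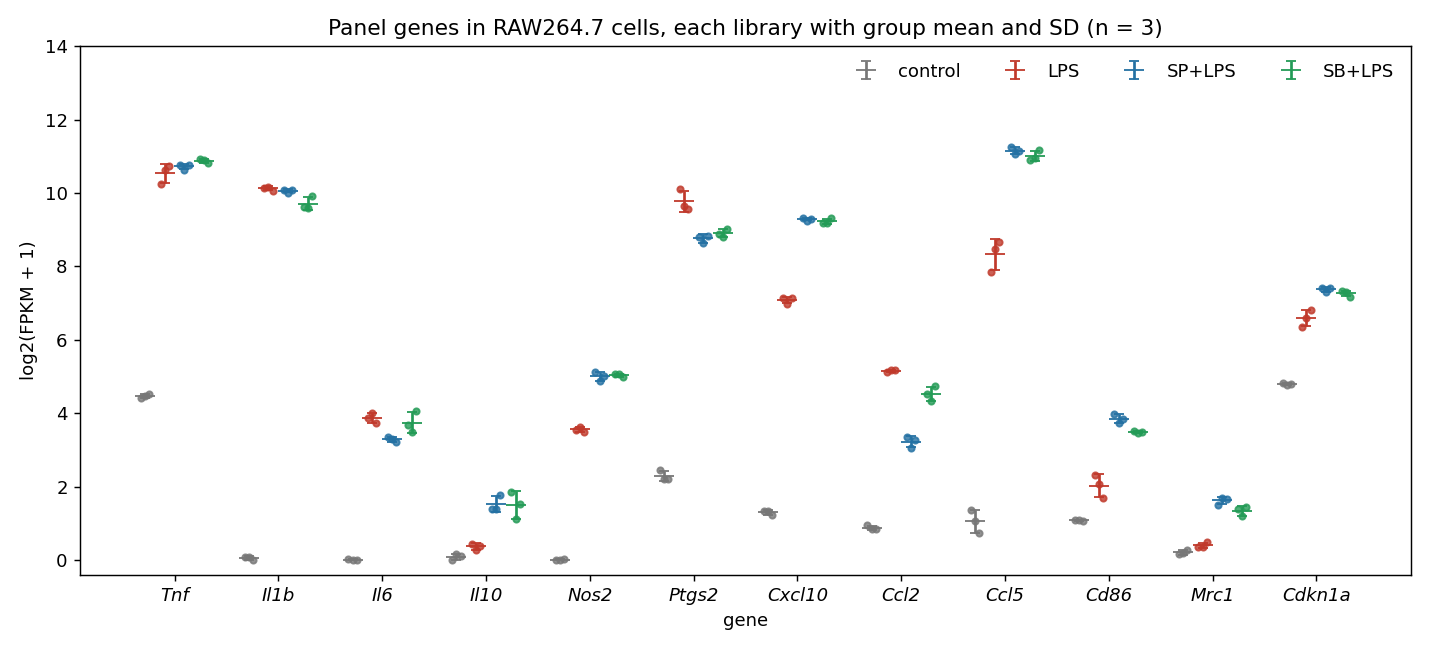
Expression of 12 macrophage genes as log2(FPKM + 1) in control, LPS, SP+LPS and SB+LPS; each point is a library, and bars show the mean and SD of 3 libraries. Cxcl10 lies at 1.46, 135, 625 and 601 FPKM in the 4 groups, while Tnf changed from 21.2 FPKM in control to 1505 with LPS.

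SP+LPS against LPS asks what propionate does to the transcriptome of LPS-treated macrophages. Interferon-stimulated genes stood higher in SP+LPS than with LPS alone, and a part of the inflammatory genes lower. The dose and time of LPS, and any pre-incubation, are not stated for the LPS group. An effect of propionate therefore cannot be told apart here from a difference in LPS exposure or pre-incubation. Cxcl10, an interferon-induced chemokine, rose from 135 ± 8.6 to 625 ± 15.1 FPKM, Ccl5 from 330 ± 90.2 to 2286 ± 166 FPKM, and Rsad2 from 190 ± 30.1 to 1942 ± 62.7 FPKM. Ccl2, the monocyte attractant, fell from 34.8 ± 0.713 to 8.38 ± 0.942 FPKM, Ptgs2 from 890 ± 183 to 434 ± 32.7 FPKM, and Il6, an acute inflammatory cytokine, from 13.7 ± 1.39 to 8.78 ± 0.488 FPKM. The log2 changes were 2.20 for Cxcl10 (SE 0.0647, adjusted p = 4.43e-10), 2.83 for Ccl5 (SE 0.198, adjusted p = 2.67e-07), -1.94 for Ccl2 (SE 0.0997, adjusted p = 2.39e-08), -1.02 for Ptgs2 (SE 0.130, adjusted p = 3.46e-05) and -0.58 for Il6 (SE 0.122, adjusted p = 0.00144). Tnf stood at 1694 ± 91.2 FPKM against 1505 ± 264 (0.18, adjusted p = 0.164). It was called higher without LPS 3 (0.29, adjusted p = 0.0315), and its change was 0.0351 without LPS 1 (adjusted p = 0.644). Il1b stood at 1068 ± 31 FPKM against 1118 ± 41.4 (-0.06, adjusted p = 0.518).

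All 42 interferon-stimulated genes rose with propionate (median 1.21, camera adjusted p = 1.33e-16), and Ifnb1, the type I interferon gene, rose from 5.92 ± 1.48 to 34.5 ± 2.02 FPKM. Cytokine genes went both ways, 8 higher and 7 lower of 20 (median 0.19, adjusted p = 0.348): the monocyte growth factor Csf1 (2.36) and Il15 (2.02) rose, and the granulocyte growth factors Csf3 (-1.55) and Csf2 (-1.37) fell. Chemokine genes were 10 higher and 5 lower of 15 (median 0.35, adjusted p = 0.0751), and the list was called higher at a mean FPKM of at least 5 (adjusted p = 0.0356) and with voom (adjusted p = 0.0413). Of 16 M1 effectors 13 rose and 3 fell (median 0.88, adjusted p = 0.00157; adjusted p = 0.136 with an estimated correlation). Nos2 rose from 10.8 ± 0.522 to 31.2 ± 2.69 FPKM and the co-stimulatory gene Cd86 from 3.12 ± 0.872 to 13.5 ± 1.254 FPKM, whereas Ptgs2, the formyl peptide receptor Fpr1 and the NADPH oxidase gene Cybb fell. Of 24 genes of the NF-kB list 15 rose and 5 fell (median 0.35, adjusted p = 0.0308; adjusted p = 0.541 with an estimated correlation). Of 9 M2 markers 8 rose and 1, Egr2, fell (median 1.48, adjusted p = 0.000208), among them Tgm2, a transglutaminase (1.66 ± 0.161 to 21.9 ± 1.93 FPKM), the transcription factors Klf4 (2.49) and Irf4 (1.87), and Mrc1 (1.23). These 9 are the members of 22 listed that passed the filter, which can admit a gene through the metabolite libraries alone and so favours rises. Mrc1 was such a gene, at 0.319 FPKM with LPS and 2.09 with propionate. Arg1, below the filter, stood at 0.338 and 0.331 FPKM. Il10 rose from 0.293 ± 0.0755 to 1.90 ± 0.464 FPKM. Of 13 inflammasome and pyroptosis genes 11 rose (median 1.08, adjusted p = 0.000104), including Pstpip1 (1.43), Ninj1, which ruptures the membrane in lytic death (1.37), and Nlrc4, a sensor of bacterial proteins (1.18).

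Proliferation, sterol and lysosome genes also shifted with propionate. All 24 G2/M genes fell (median -2.28, adjusted p = 1.69e-15), with Mki67 at 6.90 ± 0.878 FPKM against 55.2 ± 17.5 in LPS and the mitotic cyclin Ccnb1 at 6.88 ± 0.256 against 50.5 ± 5.02. Of 23 G1/S genes 22 fell (median -1.17, adjusted p = 9.99e-10), among them the helicase subunits Mcm3 (-2.33) and Mcm4 (-2.25). The other, Ccne1, was called higher (0.24, adjusted p = 0.0381), a call lost without any 1 of 7 libraries (adjusted p from 0.0535 to 0.114). Of 22 cholesterol synthesis genes 18 fell and 1, Dhcr7, rose (median -0.99, adjusted p = 8.3e-07), among them Cyp51 (-1.97) and Insig1 (-1.88). Of 22 lysosome and phagosome genes 19 rose and 2 fell (median 0.97, adjusted p = 7.16e-07), including the protease Ctsl (37.4 ± 1.73 to 176 ± 6.37 FPKM), and 7 of 10 genes of the osteoclast list rose (median 0.78, adjusted p = 0.00122), including Acp5, tartrate-resistant acid phosphatase (2.98). Cpt1a, which admits fatty acids to mitochondria for oxidation, rose from 2.36 ± 0.0546 to 25.8 ± 1.21 FPKM (log2 change 2.996, SE 0.0590, adjusted p = 6.24e-11). Slc16a1, a transporter of short-chain acids, fell from 59.2 ± 6.17 to 25.9 ± 0.46 FPKM. The largest rises were Gbgt1, a glycosyltransferase gene (ENSMUSG00000026829, chromosome 2 from 28496891 to 28505415), from 0.289 ± 0.194 to 45.8 ± 3.3 FPKM, and the neighbouring gene Gm10134 (4.95), followed by Ifit1bl1 (3.94) and the heat shock gene Hspa1b (3.91). Lsm5, the largest fall at -2.92, stood at 3.03 ± 2.98 FPKM, an SD as large as its mean.

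Limma called 3800 genes higher and 3877 lower in SP+LPS than in LPS, 1195 and 708 of them by at least 2-fold. Of the 31 lists 20 were called, and 8 also with an estimated correlation: interferon-stimulated, M2, inflammasome, G1/S, G2/M, cholesterol synthesis, lysosome and osteoclast genes. Of the 983 genes raised at least 2-fold by LPS, 252 were lower and 498 higher with propionate (median 0.32), and of the 620 lowered at least 2-fold, 135 were lower and 318 higher (median 0.32). Without SP+LPS 2 and SB+LPS 2, the libraries with reads in the largest number of genes, all 42 interferon-stimulated genes remained higher.

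SB+LPS against LPS asks the same of butyrate, with the same limit on LPS exposure and pre-incubation. With butyrate Cxcl10 rose from 135 ± 8.6 to 601 ± 29.4 FPKM, Ccl5 from 330 ± 90.2 to 2060 ± 204 FPKM and Rsad2 from 190 ± 30.1 to 1744 ± 69.3 FPKM. Nos2 rose from 10.8 ± 0.522 to 31.9 ± 0.845 FPKM and Il10 from 0.293 ± 0.0755 to 1.89 ± 0.744 FPKM. Ptgs2 fell from 890 ± 183 to 480 ± 38.2 FPKM, Ccl2 from 34.8 ± 0.713 to 22.3 ± 3.17 FPKM, and Il1b from 1118 ± 41.4 to 841.9 ± 112 FPKM. The log2 changes were 2.15 for Cxcl10 (SE 0.0647, adjusted p = 1.14e-09), 1.48 for Nos2 (SE 0.0678, adjusted p = 1.79e-08), -0.87 for Ptgs2 (SE 0.130, adjusted p = 0.000148), -0.63 for Ccl2 (SE 0.0997, adjusted p = 0.000233) and -0.42 for Il1b (SE 0.0826, adjusted p = 0.00119). Tnf was called higher at 1884 ± 73.5 FPKM (0.34, adjusted p = 0.0203), and the call was lost without SB+LPS 1 or SB+LPS 2 (adjusted p from 0.0542 to 0.0626). Il6 stood at 12.6 ± 2.73 FPKM (-0.12, adjusted p = 0.408), and was called lower without SB+LPS 3 (-0.28, adjusted p = 0.0283).

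All 42 interferon-stimulated genes rose with butyrate as well (median 1.07, camera adjusted p = 2.05e-17), with Cmpk2, a mitochondrial nucleotide kinase, at 3.28 and the antiviral GTPase Mx1 at 3.05. Of 9 M2 markers 8 rose and 1, Egr2, fell (median 1.37, adjusted p = 0.00039), with Tgm2 at 21.1 ± 0.795 FPKM and Klf4 at 4.37 ± 0.555. The limit that the filter sets on this list holds here too, with Mrc1 at 1.53 FPKM and the untested Arg1 at 0.326. Of 13 inflammasome genes 12 rose (median 0.63, adjusted p = 8.57e-05). Of 16 M1 effectors 12 rose and 2, Ptgs2 and Fpr1, fell (13 and 2 adjusted over the list alone; median 0.69, adjusted p = 0.000459; adjusted p = 0.102 with an estimated correlation). Of 20 cytokine genes 10 rose and 2 fell (median 0.34, adjusted p = 0.0439; adjusted p = 0.411 with an estimated correlation), a list call lost without LPS 1 (adjusted p = 0.12) or SB+LPS 3 (adjusted p = 0.0938) and with protein-coding genes alone (adjusted p = 0.0639). Chemokine genes were 9 higher and 4 lower of 15 (median 0.46, adjusted p = 0.0303; adjusted p = 0.397 with an estimated correlation), a call lost without SB+LPS 3 (adjusted p = 0.0866), with quantile normalization (adjusted p = 0.0587) and with protein-coding genes alone (adjusted p = 0.108). Of 24 genes of the NF-kB list 11 rose and 4 fell (median 0.19, adjusted p = 0.0712), and the list was called higher without LPS 2 (adjusted p = 0.0464) or LPS 3 (adjusted p = 0.0351), with no filter (adjusted p = 0.00632), at a mean FPKM of at least 5 (adjusted p = 0.0468) and with quantile normalization (adjusted p = 0.0309).

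All 24 G2/M genes fell with butyrate (median -1.22, adjusted p = 1.82e-12), with Cdc20, a mitotic activator of protein breakdown, at 14.8 ± 1.29 FPKM against 50.4 ± 7.63, and 17 of 23 G1/S genes fell and 1, Ccne1, rose (18 and 1 adjusted over the list alone; median -0.75, adjusted p = 2.78e-06). The Ccne1 call (0.27, adjusted p = 0.0255) was lost without LPS 1, LPS 2, SB+LPS 1 or SB+LPS 2 (adjusted p from 0.0604 to 0.0879). Of 22 cholesterol synthesis genes 18 fell and 1, Dhcr7, rose (median -0.97, adjusted p = 3.73e-07), including the sterol transfer gene Stard4 (-1.67), and Fasn, fatty acid synthase, fell by 1.79. Of 22 lysosome and phagosome genes 20 rose and 1, Atp6v1h, fell (median 0.88, adjusted p = 7.03e-08), and 8 of 10 osteoclast genes rose (median 0.65, adjusted p = 0.000533). Cpt1a rose from 2.36 ± 0.0546 to 17.4 ± 0.637 FPKM and the sterol exporter Abcg1 by 2.003. The largest rises were again Gbgt1 (4.75) and Gm10134 (4.45), then Adap2 (3.60), Hspa1b (3.60) and the integrin Itgb7 (3.36). The largest falls were Bcl2a1a (-2.16), a member of a family of close paralogs, the sialyltransferase gene St3gal6 (-2.08) and Il1rl1, the IL-33 receptor (-2.04).

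Limma called 3587 genes higher and 3464 lower in SB+LPS than in LPS, 945 and 344 of them by at least 2-fold. Of the 31 lists 21 were called, and 8 also with an estimated correlation, the same 8 lists as for propionate. Of the 983 genes raised at least 2-fold by LPS, 226 were lower and 478 higher with butyrate (median 0.26), and of the 620 lowered at least 2-fold, 95 were lower and 320 higher (median 0.35). Without SB+LPS 3, 3438 genes were higher and 3258 lower than in LPS, all 42 interferon-stimulated genes remained higher and all 24 G2/M genes lower.

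**Figure D2:**
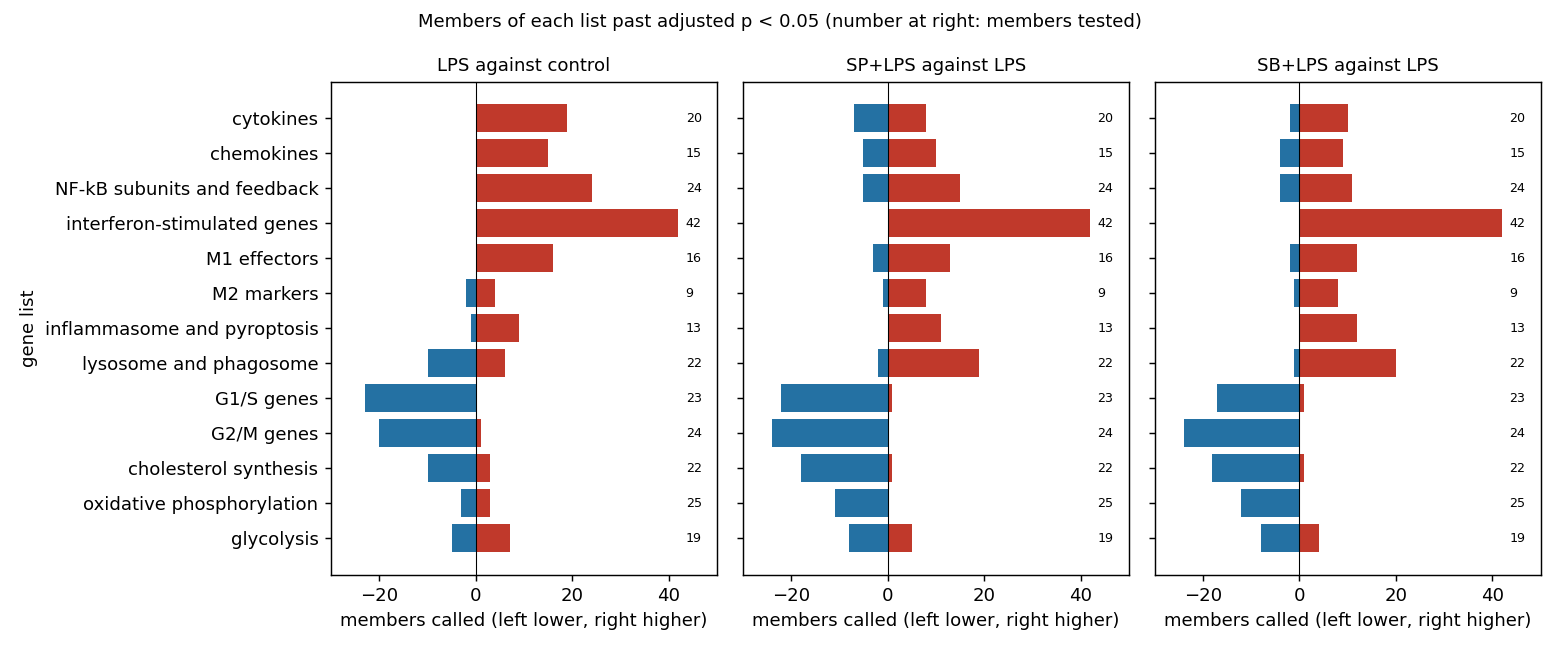
Number of tested members of 13 gene lists past an adjusted p of 0.05, higher to the right and lower to the left, in LPS against control, SP+LPS against LPS and SB+LPS against LPS, with the number tested at the right. All 42 interferon-stimulated genes are higher in the 3 comparisons, and all 24 G2/M genes are lower in both metabolite comparisons.

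SB+LPS against SP+LPS asks whether the 2 acids differ. Most of the change from LPS was shared, and the clearest difference was that proliferation genes stood higher with butyrate. Any difference in LPS exposure or pre-incubation from the LPS group would be shared too. Mki67 was 21.0 ± 1.04 FPKM with butyrate and 6.90 ± 0.878 with propionate, and Ccnb1 was 18.4 ± 1 and 6.88 ± 0.256 FPKM. Ccl2 was 22.3 ± 3.17 FPKM with butyrate and 8.38 ± 0.942 with propionate, and Edn1, the vasoconstrictor peptide gene, was 5.83 ± 0.173 and 1.296 ± 0.318 FPKM. Plet1, a surface protein gene, was lower with butyrate at 4.59 ± 0.278 against 13.1 ± 0.222 FPKM. The log2 differences were 1.48 for Mki67 (SE 0.165, adjusted p = 0.000253), 1.298 for Ccnb1 (SE 0.0730, adjusted p = 3.64e-06), 1.31 for Ccl2 (SE 0.0997, adjusted p = 2.03e-05), 1.58 for Edn1 (SE 0.1, adjusted p = 7.49e-06) and -1.33 for Plet1 (SE 0.0776, adjusted p = 4.05e-06). The doses are not given, so these values stand side by side without a match for dose.

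All 24 G2/M genes were higher with butyrate than with propionate (median 1.09, camera adjusted p = 6.43e-39), as were 19 of 23 G1/S genes (20 adjusted over the list alone; median 0.59, adjusted p = 3.61e-22), among them the ribonucleotide reductase subunit Rrm2 (1.07) and Mcm3 (0.97). Both lists kept their call with an estimated correlation (adjusted p = 0.0023 and 0.00135 with an estimated correlation), and without SP+LPS 2 and SB+LPS 2 all 24 and 14 of 23 members were called. Of 9 M2 markers 2 were lower with butyrate (median -0.24, adjusted p = 0.00132; adjusted p = 0.0478 with an estimated correlation): Klf4 (-0.88, adjusted p = 0.000274) and Irf4 (-0.28, adjusted p = 0.0484). The Irf4 call was lost without any 1 of control 1, control 2, control 3, LPS 2, LPS 3, SP+LPS 1, SP+LPS 3, SB+LPS 1 or SB+LPS 3 (adjusted p from 0.0549 to 0.172). Of 42 interferon-stimulated genes 8 were lower with butyrate, among them Ifit3b (-0.62), Gbp2 (-0.52) and Igtp (-0.41); adjusted over the list alone 13 were lower and 2 higher. That list had a median of -0.15 (adjusted p = 2.17e-06; adjusted p = 0.246 with an estimated correlation), and 3 members were lower without SP+LPS 2 and SB+LPS 2 and 18 without LPS 1. Cytokine genes were 7 higher and 3 lower of 20 (7 and 6 adjusted over the list alone; median 0.13, adjusted p = 0.213, or 0.00492 with no filter): the growth factor genes Csf2 (1.22) and Csf3 (0.97) and the IL-6 family genes Osm (1.15) and Lif (0.86) were higher with butyrate, and Ifnb1 was lower (-0.79, adjusted p = 0.00207).

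Other panel genes did not pass the test of the difference, with 95% intervals that ran from -0.12 to 0.18 for Nos2, -0.20 to 0.08 for Cxcl10, -0.09 to 0.39 for Tnf, -0.14 to 0.43 for Ptgs2, -0.42 to 0.36 for Il10, -0.04 to 0.21 for Acod1, -0.59 to 0.28 for Ccl5 and -0.32 to 0.10 for Cdkn1a. Calls for 4 panel genes lay close enough to the threshold to be lost when any 1 of several libraries was left out. Il6 was higher with butyrate (0.46, adjusted p = 0.0409), a call lost without any 1 of the 3 control or the 3 SP+LPS libraries, SB+LPS 1 or SB+LPS 3 (adjusted p from 0.0633 to 0.131). Cxcl2 (0.52, adjusted p = 0.0197) was lost without SP+LPS 1, SP+LPS 2, SP+LPS 3 or SB+LPS 1 (0.0509 to 0.0755), and Il1rn (0.40, adjusted p = 0.0262) without SP+LPS 1, SP+LPS 2 or any SB+LPS library (0.0541 to 0.0984). Il1b was lower (-0.35, adjusted p = 0.023), a call lost without SP+LPS 1, SP+LPS 3, SB+LPS 1 or SB+LPS 2 (0.0776 to 0.0969). Cd86 (-0.37, adjusted p = 0.115) was called without LPS 1 or LPS 3 (0.0241 and 0.018), Hcar2 (0.36, adjusted p = 0.0621) without the same libraries (0.00469 and 0.0466), and Nlrp3 (0.17, adjusted p = 0.0988) without LPS 1 (0.0371).

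Limma called 626 genes higher and 409 lower in SB+LPS than in SP+LPS, 53 and 18 of them by at least 2-fold. Across genes, which are not independent replicates, the changes from LPS with the 2 metabolites had r = 0.940, against 0.495 on average in 50 simulated draws in which neither metabolite changed a gene and the LPS libraries were shared. Higher than in LPS with both were 3275 genes, and lower with both 3148, against 1110 and 1093 for independent calls, a figure that leaves out the sharing of the LPS libraries. In each of those 50 draws limma called 0 genes in both. That follows from drawing no change, with noise independent between genes, and does not gauge the overlap. Of the 1035 genes called different, 1021 were also called against LPS with propionate or butyrate. Among these, 857 had changes of the same sign with the larger one in propionate, 87 with the larger one in butyrate, and 77 had changes of opposite sign. The counts moved when 1 library was left out. Without LPS 1, which is in neither group, they were 1186 and 879. The lower count was 204 without SP+LPS 1, 222 without SP+LPS 3, 234 without SB+LPS 1 and 216 without SB+LPS 2. Without both SP+LPS 2 and SB+LPS 2 the counts were 285 and 155. Of the 31 lists 5 were called, 3 with an estimated correlation, and 9 were called without SB+LPS 3.

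**Figure D3:**
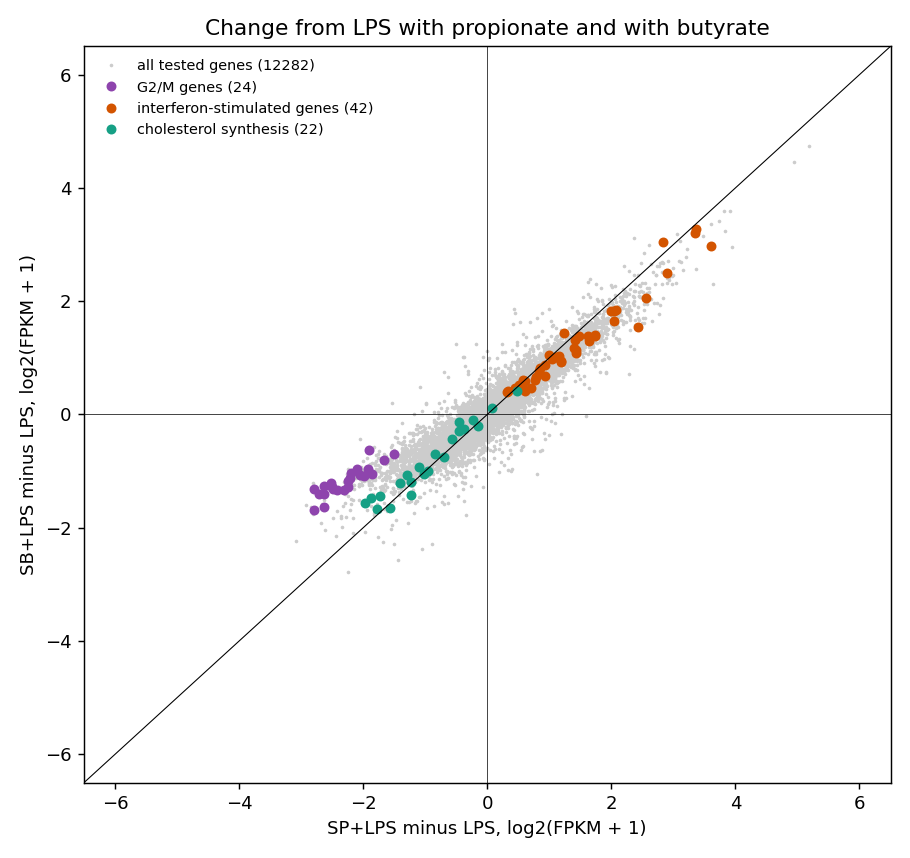
Log2 change from LPS with propionate (horizontal) and butyrate (vertical) for 12282 genes, with G2/M, interferon-stimulated and cholesterol synthesis genes coloured and the line of equal change drawn. The 24 G2/M genes lie above the line, with medians of -2.28 for propionate and -1.22 for butyrate, while the 42 interferon-stimulated genes lie near it at 1.21 and 1.07.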

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

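Chosen only after the results were seen were the tests of RNA from another cell type, sequencing depth and metabolite treatment for the background reads, the comparison of X with Y genes there, and all 3 tests of the G2/M difference. Groups of 3 libraries were not tested for single samples far from the rest. Among all results of SB+LPS against SP+LPS, those given here are genes called in opposite directions from LPS and lists whose difference held with an estimated correlation, a selection made for this part.

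The response of 3 gene lists differed between the metabolites, with median log2 differences (SB+LPS minus SP+LPS) of 1.09 for G2/M genes, 0.59 for G1/S genes and -0.24 for M2 markers. G2/M genes fell less with butyrate, and a uniformly weaker response to butyrate, background reads in 2 libraries and scaling between libraries were weighed against a difference between the acids. Over the 24 G2/M genes the slope of butyrate on propionate changes was 0.518 (0.502 to 0.529 with 1 library left out), below the 0.796 of all tested genes (0.782 to 0.810), which a uniformly weaker response forbids. All 24 members stayed called without SP+LPS 2 and SB+LPS 2, and the lowest median under other scalings was 1.08, so neither background reads nor scaling accounts for it. Neither check could readily have come out otherwise. Background in SP+LPS 2 was equal to 0.0916 FPKM, and the median difference of all genes ran only from -0.00245 with quantile normalization to 0.0247 with summed reads. A difference between the acids in their effect on cell cycle genes remains as a hypothesis, and a difference in dose stays open because doses are not given; a series of matched doses would test both. Slopes below that of all genes were not confined to the cell cycle: of 31 lists 9 had one, with no spread computed beyond G2/M, namely 0.550 for G1/S, 0.590 for propionate metabolism, 0.652 for the unfolded protein response, 0.703 for cytokines, 0.727 for MHC class II, 0.739 for apoptosis, 0.776 for inflammasome and 0.779 for osteoclast genes. The slope of M2 markers, 0.858, was not below that of all genes, and 2 of their 9 members were called. For that list a uniformly weaker response to butyrate stays open.

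Of genes called in opposite directions from LPS, with the difference SB+LPS minus SP+LPS tested itself, there were 5. H1f0, a linker histone gene on chromosome 15 from 79028450 to 79030504, changed by -0.32 with propionate and 0.77 with butyrate, a difference of 1.09 (adjusted p = 2.48e-05). Cdc25b, a phosphatase that starts mitosis, on chromosome 2 from 131186949 to 131198497, changed by -0.70 and 0.23, a difference of 0.94 (adjusted p = 2.83e-05), and its butyrate call was lost without LPS 1, SB+LPS 1 or SB+LPS 2 (adjusted p from 0.0514 to 0.0799). Gm19244, a processed pseudogene on chromosome 6 from 57617025 to 57617277, changed by 0.86 and -0.64, a difference of -1.49 (adjusted p = 0.00342). Its butyrate call was lost without any 1 of control 1, control 2, LPS 1, LPS 2, SP+LPS 2, SB+LPS 1, SB+LPS 2 or SB+LPS 3 (adjusted p from 0.0517 to 0.159). A locus without a symbol on chromosome 18 from 89836288 to 89837682 changed by 0.47 and -0.42, a difference of -0.88 (adjusted p = 0.00127), and another on chromosome 11 from 86811743 to 86816448 by 0.48 and -0.38, a difference of -0.86 (adjusted p = 3.87e-05).

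Olfactory and vomeronasal receptor genes, which lay outside the comparisons, had reads in 54.7% of 1780 genes in SP+LPS 2 and 21.1% in SB+LPS 2, against 2.0% to 4.4% in the other 10 libraries. Depth cannot account for this, since SP+LPS 2 held 14065940 reads, the fewest of 12, nor can the metabolites, since the other metabolite libraries reached 4.10% against 4.38% in control and LPS. Reads per kilobase over otherwise silent X genes were 0.475 of those over silent autosomal genes (95% interval from resampling genes 0.426 to 0.529) in SP+LPS 2 and 0.573 (0.464 to 0.686) in SB+LPS 2, and over silent Y genes 0.242 (0.201 to 0.288) and 0.195 (0.140 to 0.260). Genomic DNA stays open: a male line with 1 X and 1 Y would give equal ratios for both, and genes with many copies, which were not set apart, would lower either. RNA from another cell type stays open too, since silent receptor genes had 0.391 (0.359 to 0.425, resampled likewise) of the reads per kilobase of other silent protein-coding genes in SP+LPS 2, which decides neither way. The background was equal to 0.0916 FPKM in SP+LPS 2 and 0.0162 FPKM in SB+LPS 2 over 28572 silent genes, against a filter of 1 FPKM.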

How the results depend on the processing

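Scaling to summed reads, protein-coding genes alone and leaving out SP+LPS 2 with SB+LPS 2 were chosen after seeing the data; the other alternatives were planned. Of the 26 alternatives, all but the 2-fold threshold were applied to the 565 values of named genes. These gave 13545 values with the same direction and side of the threshold, 429 no longer called, 24 newly called and 21 reversed. Genes below a stricter filter gave none. The cause was not tested except where fewer genes or libraries, or a stricter threshold, set it. Counts are given as higher, then lower. At a 2-fold threshold they were 983 and 620 for LPS against control, 1195 and 708 for SP+LPS, 945 and 344 for SB+LPS, and 53 and 18 for SB+LPS against SP+LPS; of LPS-induced genes 235 were higher and 86 lower with propionate, 198 and 66 with butyrate. The LPS-induced set was formed anew under each alternative, so its size moves these counts: 983 genes at first and at 2-fold, 756 at a mean FPKM of 5, 541 with a pseudocount of 5 and 1413 with voom. Scaling to summed reads gave 2019 and 5902 for LPS against control. A mean FPKM of at least 5 gave 1640 lower in LPS, 2043 higher in SP+LPS, 1919 higher in SB+LPS, and 167 and 148 LPS-induced genes lower with propionate and butyrate. With a pseudocount of 5, LPS-induced genes higher in SP+LPS than in LPS were 320 and lower 116, and LPS-induced genes higher in SB+LPS than in LPS were 313 and lower 102. With voom on whole reads they were 734 and 292 with propionate and 706 and 275 with butyrate. Lists called with an estimated correlation were 5, 8, 8 and 3 in the 4 comparisons; for SB+LPS against SP+LPS there were 9 with no filter, 9 with voom and 10 with fry. SB+LPS against SP+LPS gave 285 and 155 genes without SP+LPS 2 and SB+LPS 2, and 237 lower with no filter. The correlation of the metabolite changes was 0.907 at a pseudocount of 0.1, 0.956 at 5, 0.904 with no filter, 0.961 at a mean FPKM of 5, 0.935 with quantile normalization, 0.934 with voom, 0.928 without the 2 libraries and 0.962 in coding genes, judged against the SD of its leave-one-out values. With 1 library left out, SB+LPS against SP+LPS ran from 424 to 1186 higher, 204 to 879 lower and 4 to 9 lists, and the correlation from 0.929 to 0.943. LPS 1 is in neither group of that comparison, so leaving it out can reach these counts only through the shared estimate of spread, whose change is not given. Reversed for LPS against control with quantile normalization were Mrc1 (-0.0158), Bsg (-0.25), Cycs (-0.0391), Ndufa4 (-0.10), Rpl27 (-0.0469), Rpl7 (-0.0642) and Rplp0 (-0.0361), and with summed reads Bsg (-0.0341), Cycs (-0.0271) and Ndufa4 (-0.10). With quantile normalization Tnf reversed in SP+LPS against LPS (-0.0111), and Acod1 (-0.0308) and Cxcl10 (0.0158) in SB+LPS against SP+LPS. Cxcl2 in SB+LPS against LPS was 0.0566 without SP+LPS 2 and SB+LPS 2, and ran from -0.21 to 0.0566 with 1 library left out. In SB+LPS against SP+LPS without both, Il10 was 0.11 and Nos2 -0.0444; with 1 library left out Il10 ran from -0.21 to 0.17 and Nos2 from -0.0322 to 0.0883. Replicate number as a block gave 3655 and 3288, 3743 and 3846, 3516 and 3402, and 540 and 318. The 18 same-number pairs had residual correlations from -0.093 to 0.142, with a median of -0.00512 against -0.000358 for other pairs. No pairing by number showed, but shared handling by number is not excluded. SP+LPS 2 and SB+LPS 2, which both held background reads, had a residual correlation of 0.103. At these depths, simulated changes of 1.5-fold, in draws with few changed genes, were recovered in 43.3% to 55.4% of genes.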

Other observations

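Chosen only after the results were seen were Malat1 and Neat1 below, the test of carried-over control RNA and the value that decides the test of an earlier LPS stage; the tests of mitochondrial transcripts and of other splits of the libraries were planned. Of 15 MHC class I genes, which load peptides for killer T cells, 14 rose and 1, Erap1, fell with propionate (median 0.67, camera adjusted p = 0.000258; adjusted p = 0.21 with an estimated correlation), and 11 rose and 1, again Erap1, fell with butyrate (0.65, adjusted p = 0.000459; adjusted p = 0.221 with an estimated correlation). The peptide transporter Tap2 changed by 2.09 and 1.68 and the immunoproteasome subunit Psmb9 by 1.48 and 1.38. Of 5 MHC class II genes 4 rose and 1, Ifi30, fell with propionate (median 1.82, adjusted p = 0.0237; adjusted p = 0.115 with an estimated correlation) and 4 rose with butyrate (1.00, adjusted p = 0.0124; adjusted p = 0.0765 with an estimated correlation), including the invariant chain Cd74 (1.82 and 1.28) and H2-DMa (2.14 and 1.86). Of 18 macrophage identity genes 15 rose and 1, Fcgr2b, fell with propionate (0.85, adjusted p = 7.06e-05; adjusted p = 0.115 with an estimated correlation) and 13 with butyrate (14 higher and 1 lower adjusted over the list alone; 0.80, adjusted p = 3.12e-05; adjusted p = 0.0892 with an estimated correlation), with Cebpb at 2.37 and 2.08 and the pore-forming gene Mpeg1 at 1.85 and 1.73.

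Of 17 targets of NRF2, the oxidant response factor, 10 rose and 4 fell with propionate (median 0.66, adjusted p = 0.0192; adjusted p = 0.347 with an estimated correlation), and 11 rose and 3 fell with butyrate (0.35, adjusted p = 0.0116; adjusted p = 0.313 with an estimated correlation), with Srxn1 at 1.64 and 1.44. Of 21 MAPK genes 14 rose and 2 fell with propionate (0.54, adjusted p = 0.00157; adjusted p = 0.126 with an estimated correlation), and 13 and 2 with butyrate (13 and 3 adjusted over the list alone; 0.50, adjusted p = 0.00143; adjusted p = 0.116 with an estimated correlation), led by the phosphatase gene Dusp1 (2.002 and 2.29). Of 11 genes listed as raised by inhibitors of histone deacetylases, enzymes that both acids are known to inhibit, 8 rose and 1, H1f0, fell with propionate (0.78, adjusted p = 0.0141; adjusted p = 0.347 with an estimated correlation), and 8 rose with butyrate (0.67, adjusted p = 0.000533; adjusted p = 0.216 with an estimated correlation), with gelsolin (Gsn) at 2.54 and 2.07 and Clu at 2.10 and 1.72. H1f0 changed by -0.32 with propionate and 0.77 with butyrate, but the list was not called between the acids. Its median difference, SB+LPS minus SP+LPS, was -0.11 (camera adjusted p = 0.514), with 2 members higher and 1 lower (2 and 3 adjusted over the list alone). Of 20 genes of the unfolded protein and integrated stress response 10 rose and 4 fell with propionate (11 and 4 adjusted over the list alone; median 0.26, adjusted p = 0.0407; adjusted p = 0.347 with an estimated correlation), a call lost without SP+LPS 1 (adjusted p = 0.0539) and with protein-coding genes alone (adjusted p = 0.0665). With butyrate 11 rose and 3 fell, and the list was not called (0.38, adjusted p = 0.0771), except with no filter (adjusted p = 0.00777), at a mean FPKM of at least 5 (adjusted p = 0.0447) and with quantile normalization (adjusted p = 0.0466). Toll-like receptor signalling genes (adjusted p = 0.404 and 0.392) and immediate early genes (adjusted p = 0.509 and 0.277) were called with neither metabolite. Of markers of other cell types, none of the fibroblast, epithelial or neutrophil lists passed the filter. The immunoglobulin gene Ighm was 14.2 FPKM in control, 17.1 with LPS, 2.36 with propionate and 3.09 with butyrate. Malat1, a nuclear noncoding RNA, was 110 FPKM in control, 111 with LPS, 322 with propionate and 261 with butyrate (1.51, adjusted p = 5.03e-06, and 1.23, adjusted p = 3.62e-05, from LPS). Neat1, another nuclear noncoding RNA, fell by 1.41 with LPS, and rose by 1.958 with propionate and 1.00 with butyrate from there.

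LPS 1 stood apart from the other LPS libraries, with 12 of 13 mitochondrially encoded genes higher than in both others. An earlier stage of the LPS response is argued against by immediate early genes, whose median was lower in LPS 1 by a log2 difference of -0.219, with 13 of 18 members below both others and 1 above; the median of interferon-stimulated genes, 0.0119, had first been taken to decide this and was replaced after both were seen. The mitochondrial reads do not account for it alone, since without those genes LPS 1 was still 1.48 times as far from the others as they were from each other. Carry-over of control RNA as the whole cause is argued against by correlations across genes, which were 0.868 to 0.876 between LPS 1 and the control libraries and 0.883 to 0.889 for LPS 2 and LPS 3; a first test, in which 39% of the 100 genes most induced by LPS were higher in LPS 1 than in both others and 42% lower, had not decided it. Genes for MHC class I (-0.366, 11 of 15 below both others), the NF-kB list (-0.282, 18 of 24) and cytokines (-0.197, 12 of 20) were lower in LPS 1 too. That could go with a weaker response or, against the immediate early genes, an earlier one. Lists not called in LPS against control were lower as well: oxidative phosphorylation (-0.265, 21 of 25) and glycolysis (-0.189, 14 of 19). M1 effectors, all raised by LPS, went the other way (0.121, with 9 of 16 above both others and 6 below). G2/M genes, most of which fell with LPS, were higher in LPS 1 (0.243, with 16 of 24 above both others and 7 below). That could also go with a weaker response, but G1/S genes, which all fell with LPS, differed little (0.0528, 12 of 23 above and 9 below). What sets LPS 1 apart stays open.

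The splits of the 6 libraries of each comparison into groups of 3 number 10, too few for a share below 0.05, and in each comparison 1 of them, the real one, reached the real count. LPS against control gave 7092 genes, with 0 as the highest other split by limma; SP+LPS against LPS gave 7677 with 1, SB+LPS against LPS 7051 with 10, and SB+LPS against SP+LPS 1035 with 1.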
